A study of Mus musculus with 12 samples.

How the data were processed

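RNA was measured in cultured macrophages grown from the bone marrow of wild-type mice and of mice lacking Gpr31b, the mouse gene for GPR31, a G protein-coupled receptor that binds a 12-lipoxygenase product. Cells were unstimulated (M0) or had received LPS and IFN-γ (M1), which made 4 groups of 3 libraries, 12 in all. Polyadenylated RNA was made into strand-specific TruSeq libraries and sequenced on a NovaSeq instrument, per the labels' protocols. The deposited table holds whole-number counts per gene symbol and library, not normalized, per the file headers. Trimmomatic, FastQC, HTSeq, DESeq2 and the mm10 build are listed per the submitters' processing notes, which give no versions. The aligner, the gene annotation and the strand setting of the counting were not given in the sources used here.

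The table had 24552 rows, of which 11497 held a count in at least 1 library. Library totals ran from 372878 to 585465 counts, with a median of 427858. Spreadsheet software had turned 26 symbols into dates, which held 0.01% of all counts, and 2 row names occurred again. These rows kept their place in the library sizes. Symbols were matched to GENCODE M21, an annotation of the build GRCm38 that mm10 also names, and 24109 rows matched 1 gene each. Matched rows held 92.04% of the counts. For each matched row the genes on the opposite strand whose exons overlapped its own exons by 20 or more bases were listed, and, where there was none, an opposite-strand gene whose 3′ end lay within 5000 bases. Values are given by row, since the table does not say on which strand reads were counted. The gene of an overlapping opposite-strand exon is named where a row is first described. A nearby 3′ end is named for a few rows only, so other rows may also lie past such an end.

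Rows were tested with edgeR 4.0.16 under R 4.3.3. Low rows were removed with filterByExpr on the 4 groups, which left 2333 rows. TMM factors scaled the libraries, a quasi-likelihood model with robust spread was fitted to all 12 libraries, and 5 comparisons were drawn from it: M1 against M0 in wild type, M1 against M0 in knockout, knockout against wild type in M0, the same in M1, and the interaction of genotype with stimulation. The p-values were adjusted by Benjamini and Hochberg's method over all tested rows of a comparison, and a row was called at an adjusted p under 0.05. Levels are CPM, counts scaled to a common library size, with the TMM factors applied, given as mean ± SD over 3 libraries. Standard errors and 95% intervals of the log2 fold change were worked back from the fold change and the test statistic of the same model. Where a group is near 0 they can be too small, since few counts then set the fold change. Where all libraries of a group were at 0, the fold is given as at least a value, taken against 3 counts over that group. That limit covers counting error alone and takes counts as independent. Of counts from 1 to 12, 60.9% were even, with 14802 counts of 2 and 9131 of 1. Counts may therefore not be independent. Such folds may then be too high, and limits on a count of 0 too low. The counts of the other group enter as they stand, so such a fold leaves out their counting error and the spread between libraries. Apart from groups near 0, intervals cover counting error and the spread between libraries only. PCR reads without molecular identifiers are not independent molecules. The labels do not say that libraries come from separate animals, so all p-values measure the spread between these libraries.

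The model was tested on simulated counts with 200 changed rows per comparison. Of the rows changed 2-fold and at 100 CPM or more, 90% were recovered for wild-type stimulation, 75.8% for knockout stimulation, 70.8% for genotype in M0, 74.1% for genotype in M1 and 71.4% for the interaction. Over all levels the share for a 2-fold change was 28.4% in M0, 29.9% in M1 and 23.9% for the interaction. The simulation was not repeated. At 100 CPM or more its shares rest on 30, 33, 24, 27 and 21 changed rows, in the order of the comparisons. For stimulation the simulated states differed in the 200 rows alone, whereas in the data 1138 and 1110 rows were called. Those shares therefore do not cover so large a shift between states.

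Gene lists for macrophage programs, for other cell types and for technical checks were fixed first, 45 in all. Each was tested with camera in limma 3.58.1 on voom values of the same 4-group design, with a preset correlation of 0.01 and adjustment over the program lists of a comparison. Lists with under 5 measured members received counts only, which left 20 program lists with a test. The named rows were the 10 with the largest rise and the 10 with the largest fall per comparison among called rows with a mean of 5 CPM or more in a group and no overlap between the libraries compared. Provisional symbols and ribosomal pseudogenes were skipped there. To these came Gpr31b, up to 2 rising and 2 falling members of each list described, and a fixed set of macrophage activation genes. A member of that set is not reported here. Any other row named is said to have been chosen after its values were seen.

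The comparisons, tests, lists and naming rule were chosen before the data were examined, as were most alternatives: other scaling (DESeq2 size factors, library size alone), other filters, DESeq2 1.42.0, limma-voom, a 2-fold threshold, a block for the replicate number or for the line label, fits of the compared groups alone and the removal of each library in turn. Added after the data were seen were 5 settings: rows summed by their opposite-strand gene, counts halved, removal of the 10 highest rows, and the rows with and without an opposite-strand exon taken apart. Gene lists were also read by the opposite-strand gene and in rows without such an exon, again chosen after the data were seen. Reads were not used here.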

Results

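Bone-marrow-derived macrophages of wild-type (WT) and Gpr31b knockout (KO) mice were profiled without stimulation (M0) and after LPS with IFN-γ (M1), the classical proinflammatory stimulus, with 3 libraries in each of the 4 groups. The total count was 471467, 396676 and 465350 in the WT M0 libraries, 585465, 395050 and 372878 in WT M1, 432092, 423623 and 410131 in KO M0, and 396945, 445722 and 455160 in KO M1. The highest total was 1.57 times the lowest. Between 4787 and 6216 rows held a count in each library. Stimulated libraries were more concentrated: their 10 highest rows took 32.2% to 34.5% of the counts, against 20.7% to 22.1% in M0. In M1 the AV051173 row alone held 9.21% to 13.1%. Replicate libraries of a group correlated at 0.924 to 0.958 across rows, on the log2 CPM scale, and the first principal component held 72.1% of the variance.

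Counts lay mostly in rows with another gene on the opposite strand. Of the 68 matched rows with a mean of 1000 counts or more, 67 (98.5%) had an opposite-strand exon, as did 396 of 443 rows (89.4%) with 100 to under 1000 counts and 1597 of 12736 rows (12.5%) at 0. Exons of another gene on the same strand showed no such gradient, at 7.35% of the highest rows and 7.41% of the rows at 0. Rows with an opposite-strand exon held 91% of the matched counts. Of rows without one, 264 of 475 (55.6%) with a mean of 10 counts or more lay within 5000 bases past an opposite-strand 3′ end. Among such rows at 0 the share was 17.8%. Genes that macrophages express strongly had few counts in their own rows: 40 rows for cytosolic ribosomal proteins held 0.0546% of all counts, and 22 rows for macrophage identity genes, such as Csf1r (opposite Hmgxb3) and Adgre1, held 0.0992%. Levels below are therefore given by row. As a set, the shares above argue against the high rows having been filled mainly by reads of their own genes. For a single row that overlaps an abundant opposite-strand gene, the table does not show which of the genes gave the reads.

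**Figure D1:**
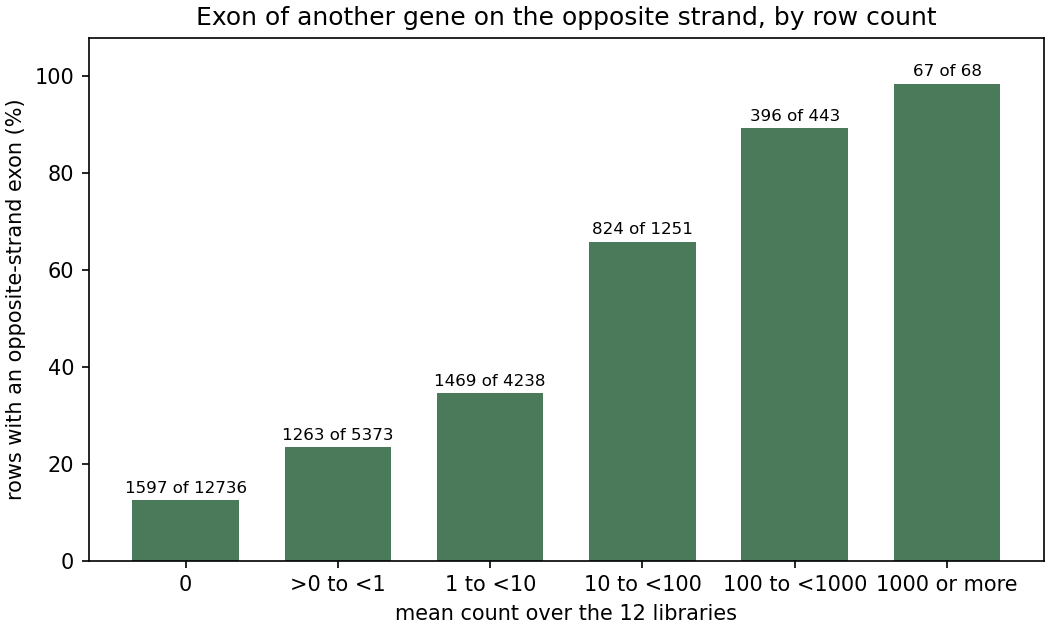
Share of matched rows with an exon of another gene on the opposite strand (y axis, percent), by the row's mean count over the 12 libraries (x axis), with the number of rows above each bar. The share was 12.5% among rows at 0 and 98.5% among rows with 1000 counts or more.

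The targeted gene, Gpr31b (chromosome 17, 13051014 to 13052296, minus strand), had few counts. Its row held 2 counts in each of the 3 WT M1 libraries and 0 in the other 9. Set against the limit of 3 counts in KO M1, the 6 counts in WT M1 are a row level 1.97-fold higher. The error of the 6 counts is left out, so a smaller difference is not excluded. In rows with no gene on the opposite strand, 64.2% of counts from 1 to 12 were even. The 6 counts may therefore not be independent, and the limit of 3 may be too low. Without the TMM factors, a count of 0 over the KO M1 group allows up to 2.31 CPM, and over the KO M0 group up to 2.37 CPM. The row was too low to be tested, and no gene was found opposite it. The labels do not say which part of the gene is missing in the knockout, and other genes had few counts in their own rows, so the row does not measure the level of the gene and is a weak check of the genotypes.

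The first comparison asked how wild-type macrophages responded to LPS and IFN-γ. Rows of interferon targets and chemokines were among those with the largest rises. The Mir6381 row, which overlaps an exon of the interferon-γ-induced GTPase gene Gbp2 on the opposite strand (chromosome 3, 142623860 to 142623946), went from 131 ± 17.4 to 71500 ± 1445 CPM (n = 3 each), a log2 fold change of 9.09 with a standard error of 0.15 (adjusted p = 9.36e-22). The row of the T-cell chemokine Cxcl9 went from 0 to 702 ± 151 CPM, at least 370-fold higher (adjusted p = 8.80e-18). The largest falls were in the Nat8l, Ccdc152 and Prune2 rows. The Nat8l row was at least 64.3-fold lower (from 177 ± 21.2 CPM to 0). The Ccdc152 row, opposite the selenium carrier gene Selenop, was at least 63.8-fold lower (to 0). The Prune2 row fell from 1778 ± 4.4 to 4.1 ± 5.42 CPM (log2 fold change −8.82, standard error 0.29, edgeR adjusted p = 9.36e-22). Its WT M1 libraries held 0 to 3 counts each, so its standard error understates the counting error. Exons of the Nat8l and Prune2 rows lie 1263 and 999 bases past the opposite-strand 3′ ends of Poln and Gm27970.

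In total 1138 of 2333 rows were called, 600 higher and 538 lower in M1, and 873 of them changed at least 2-fold. The libraries of both states did not overlap in 1309 rows (56.1%, against 10% by chance). With library size alone as the scale, 1282 rows were called, 389 higher and 893 lower, and the median log2 fold change of all rows was −0.544, so directions here are relative to the TMM scale.

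Among the other rows with the largest rises, each at 0 in all WT M0 libraries, were those of Bcl2l14, opposite 4933406J09Rik (at least 308-fold), Gbp2 itself (at least 144-fold), Ifit2, an interferon-induced antiviral gene (259 ± 86.3 CPM in M1), the bacterial lipoprotein receptor gene Tlr1 (at least 120-fold), Kif1b (at least 78.1-fold), the CD30 gene Tnfrsf8 (at least 62.8-fold) and the chemokine Ccl5 (at least 62.3-fold). The Ghdc row went from 1.2 ± 2.08 to 1090 ± 193 CPM. Other falls to 0 were in the rows of Cebpa, a myeloid transcription factor gene opposite Gm45091 (at least 35.4-fold lower), Myom1, opposite the myosin light chain gene Myl12a (at least 31.5-fold), Sgsh, opposite Card14 (at least 30.6-fold), Zswim1, opposite Spata25 (at least 24.9-fold), Cnpy4 (at least 14.3-fold), Zfp704, opposite C030034L19Rik (at least 13.9-fold) and Usp40, opposite the diacylglycerol kinase gene Dgkd (at least 13.4-fold).

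Of the 20 program lists with a test, 8 were higher in M1. Measured members are those whose row passed the low-count filter. In either genotype a member is said to rise or fall by the counts of its row, which need not be reads of that gene. A row without counts in M0 passes it only through its M1 counts. The share of measured members that rose is therefore not a share of the whole list, in either genotype. The type I interferon list, for one, has 39 members. All 15 measured members of the type I interferon list rose (camera adjusted p = 3.38e-06), among them Ifit2 and Irf7 (opposite Phrf1). All 13 measured interferon-γ targets rose (adjusted p = 4.52e-06), led by Gbp2 and Iigp1. Of the 13 measured M1 markers 12 rose (adjusted p = 2.31e-06), and of 12 measured genes for MHC class I presentation, which displays peptides to cytotoxic T cells, 11 rose and 1 did not pass (adjusted p = 0.000143). In that list the Tap1 row changed by 7.06 on the log2 scale (standard error 0.47), and it lies opposite Psmb9. These 4 calls held with an estimated correlation, at adjusted p = 0.0103, 0.0419, 0.0103 and 0.0298 in the order given. Counts adjusted over the list alone were the same for these 4 lists.

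The remaining 4 list calls were lost with an estimated correlation. Chemokines rose in 4 of 5 members (adjusted p = 0.0116, and adjusted p = 0.0701 with an estimated correlation). Pattern recognition genes rose in 4 of 5, led by Tlr1 and Tlr6 (0.0441, and adjusted p = 0.139 with an estimated correlation). Oxidative stress genes rose in 9 of 15, with Prdx5 (opposite Trmt112) at 4.74 on the log2 scale (0.00621, and adjusted p = 0.225 with an estimated correlation). Glycolysis and HIF-1 targets rose in 8 of 12 and fell in 1, with Hif1a (opposite Gm15283) at 3.77 and Pfkp (opposite Pitrm1) at −0.64 (0.0281, and adjusted p = 0.276 with an estimated correlation). The lysosome list, with 5 members up and 4 down of 20, was not called (camera adjusted p = 0.67): Ctsd, a lysosomal protease gene, changed by −2.90 (standard error 0.28) and Fcgr1 by 3.19 (standard error 1.04). Macrophage identity genes also went both ways, with 6 up and 4 down of 18 (adjusted p = 0.715). Cx3cr1, opposite Gm33858, changed by −4.67 and Cd14, the LPS co-receptor gene, by 3.33. The Pfkp call was lost with DESeq2 and without WT M1 replicate 1. The Fcgr1 call was lost without WT M0 replicate 1, without WT M0 replicate 2 or without WT M1 replicate 3.

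Among the activation genes fixed in advance, the row of Nos2, which makes nitric oxide, summed to 1 count in WT M0 and 121 in WT M1 (edgeR adjusted p = 7.34e-09). An exon of that row lies 2720 bases past the opposite-strand 3′ end of Lgals9. The rows of Il1b, opposite Il1bos (52 counts, at least 24.2-fold higher), Cxcl10, opposite Art3 (81, at least 37.7-fold) and Ptgs2, the inducible prostaglandin synthase gene (102, at least 47.4-fold), were at 0 in WT M0. Acod1, which makes itaconate, went from 3 to 228 counts (adjusted p = 3.17e-11), Cd38 from 2 to 132 (3.93e-09) and Irf1, opposite Gm17334, from 14 to 87 (4.24e-05), by edgeR with adjustment over all rows. Tnf held 0 counts in M0 and 14 in M1, and Cd86 1 and 30, too few for a test. The rows of Il6, Cd80, Il10 and Alox15 held no count in any library, which allows a row level up to 2.22 CPM in WT M1, without the TMM factors. Alox12, which makes the ligand of GPR31, held 4 counts in WT M0 and 2 in WT M1, Arg1 2 and 1, and Tlr4 3 and 0. As for Gpr31b, such rows do not measure the level of their genes. Few or no counts in them do not show that a gene was little expressed.

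**Figure D2:**
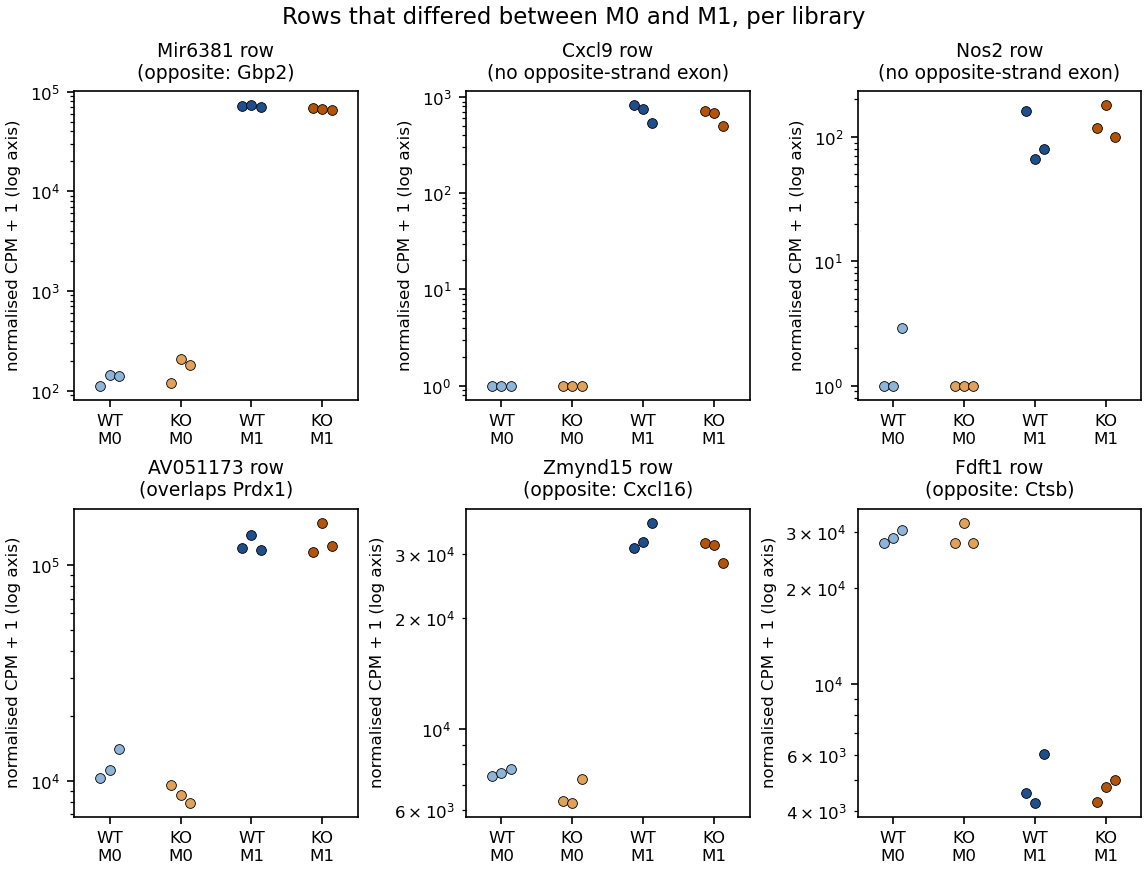
Normalised CPM plus 1 (y axis, logarithmic) of 6 rows in each of the 3 libraries of the 4 groups (x axis), each point a library. The Mir6381 row, opposite Gbp2, averaged 131 CPM in WT M0 and 71500 in WT M1, and the Fdft1 row, opposite Ctsb, averaged 29010 and 4945.

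The 10 rows with the highest mean CPM of any group were, beside Mir6381, the following, chosen after their values were seen. AV051173, whose RefSeq model overlaps the 5′ end of the peroxidase gene Prdx1 on chromosome 4, went from 11850 ± 1955 to 125300 ± 11500 CPM (log2 fold change 3.40, standard error 0.16). Zmynd15, opposite the chemokine gene Cxcl16, changed by 2.13 (0.08), Sla2, opposite Rab5if, by 2.09 (0.08), Ddb2, opposite the lysosomal phosphatase gene Acp2, by 1.80 (0.08), 3110062M04Rik, opposite Tmem140, by 1.76 (0.07), and Tmem132a, opposite the peptide transporter gene Slc15a3, by 1.05 (0.09). Fdft1, opposite the lysosomal protease gene Ctsb, changed by −2.55 (0.10), Ctsa, opposite the lipid transfer gene Pltp and Neurl2, by −2.23 (0.28), and Gm15441, opposite the thioredoxin-binding gene Txnip, by −0.70 (0.10). Of lower rows, likewise chosen, 1700071M16Rik, opposite the phospholipase gene Pla2g7, changed by 3.18 (0.33), and Oraov1, opposite the cyclin gene Ccnd1, by 2.96 (0.22). All these rows were called.

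The second comparison asked the same of knockout macrophages. The Mir6381 row went from 168 ± 45.3 to 67470 ± 1537 CPM. The Ghdc row went from 0 to 928 ± 161 CPM, at least 451-fold higher, the Cxcl9 row to 639 ± 119 CPM, at least 309-fold higher, and the Rnf219 row at least 275-fold. The Cd163 row, of the haemoglobin scavenger receptor of resting macrophages, fell from 2639 ± 659 to 6.28 ± 3.73 CPM. Its log2 fold change was −8.61 (standard error 0.47, edgeR adjusted p = 2.79e-08). The KO M1 libraries held 1 to 4 counts of it, so this standard error understates the counting error. Of the 2333 rows 588 were higher and 522 lower in M1, 1110 in all, and 836 changed at least 2-fold. The libraries did not overlap in 1289 rows (55.3%, against 10% by chance).

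Also among the largest rises were the rows of Bcl2l14 (at least 248-fold), Gbp2 (at least 124-fold), Acod1 (at least 90.2-fold), Ifit2 (at least 83.4-fold), Tnfrsf8 (at least 73.9-fold), Rsad2, the viperin gene (at least 72.1-fold), and Rarg, a retinoic acid receptor gene (at least 64-fold). Among the largest falls to 0 in KO M1 were those in the rows of Nat8l (at least 62.1-fold lower), Cul9 (at least 46.8-fold), Bach2, opposite Bach2os (at least 33.8-fold), Zswim1 (at least 28.6-fold), Sgsh (at least 26.6-fold), Dnmt3aos, opposite the DNA methyltransferase gene Dnmt3a (at least 20.9-fold), Zfp704 (at least 17.7-fold) and Zfp119a (at least 16-fold). Prune2 changed by −7.96 (standard error 0.26), with 1 to 5 counts per KO M1 library, so its standard error again understates the counting error. An exon of the Cul9 row lies 948 bases past the opposite-strand 3′ end of Dnph1.

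The same 8 program lists were called in knockout cells. All 13 M1 markers rose (camera adjusted p = 5e-07), as did all 15 type I interferon genes (6.69e-06), all 13 interferon-γ targets (8.71e-06) and 10 of 12 MHC class I genes (0.000306). With an estimated correlation these had adjusted p = 0.0071, 0.0114, 0.0457 and 0.0457. Chemokines rose in 4 of 5 (0.0203, and adjusted p = 0.0856 with an estimated correlation), pattern recognition genes in 5 of 5 (0.0211, and adjusted p = 0.0856 with an estimated correlation), oxidative stress genes in 10 of 15 (0.00149, and adjusted p = 0.153 with an estimated correlation) and glycolysis genes in 6 of 12, with 1, Pfkp, falling by 0.76 on the log2 scale (0.0363, and adjusted p = 0.329 with an estimated correlation). Adjusted over the list alone, MHC class I genes rose in 11, oxidative stress genes in 11 and glycolysis genes in 9, and 1 chemokine row, Ccl3, fell (−0.47 on the log2 scale, standard error 0.21). Nos2 held 0 counts in KO M0 and 142 in KO M1 (at least 64-fold higher), Il1b 0 and 76 (at least 34.3-fold), Cxcl10 0 and 106, Ptgs2 0 and 118, and Tnf 0 and 15. Without KO M1 replicate 3 the Tlr6 call of the pattern recognition list was lost, and without KO M0 replicate 1 the Pfkp call. With library size alone as the scale 1249 rows were called in knockout cells, 391 higher and 858 lower, and the median of all rows was −0.47.

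Both genotypes called 927 rows in the same direction and 0 in opposite directions by edgeR. Of the 927, 501 were higher and 426 lower in M1, where independent lists of these sizes would share 151.2 and 120.4. Another 211 rows were called in wild type alone and 183 in knockout alone, which does not show a difference between the genotypes, since 0 of the wild-type calls passed the interaction test. Across rows, which are not independent replicates, the log2 fold changes correlated at 0.9154, with a slope of knockout on wild type of 0.9735 over called rows.

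**Figure D3:**
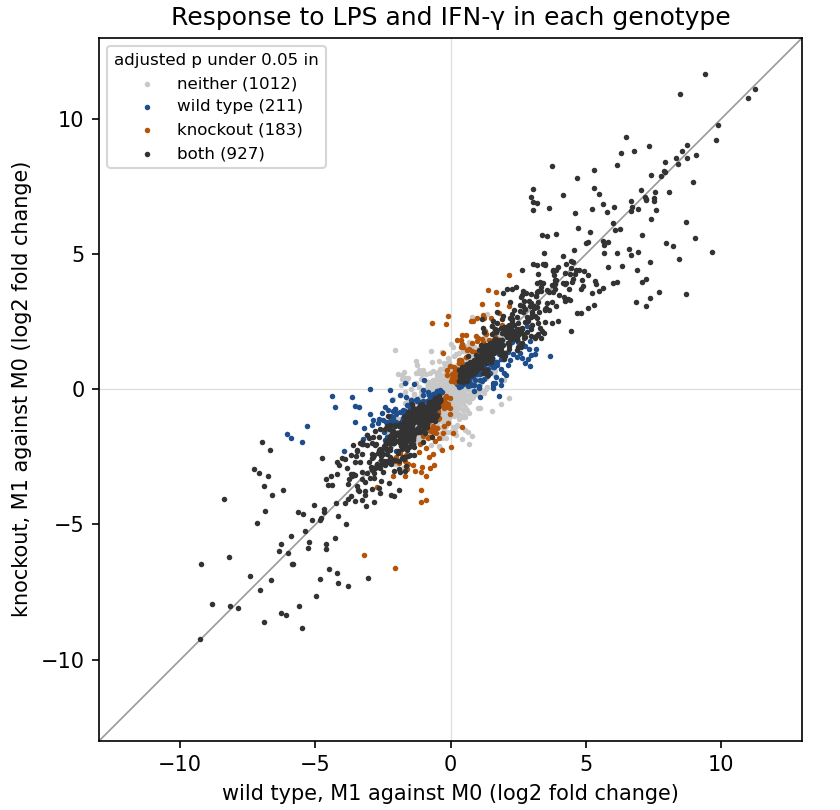
Log2 fold change of M1 against M0 in wild type (x axis) and in knockout (y axis) for 2333 rows, coloured by the genotype in which edgeR's adjusted p was under 0.05, with the line of equal change. The 927 rows called in both genotypes all lie in the quadrants of equal sign.

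The third comparison asked what the knockout changed in unstimulated cells. Only the Perm1 row was called: it was higher in knockout, at 214 ± 28.7 against 123 ± 10.8 CPM (n = 3 each), a log2 fold change of 0.79 (standard error 0.16, 95% interval 0.47 to 1.11, adjusted p = 0.0476). Perm1 codes for a regulator of muscle metabolism, and its row (chromosome 4, 156215868 to 156221307) begins 149 bases past the 3′ end of Plekhn1. Every KO M0 library lay above every WT M0 library. The call passed in 3 of 17 other settings, with adjusted p from 0.00176 to 0.602. It was lost with DESeq2, with limma-voom and without any one of the 6 M0 libraries.

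At an unadjusted p under 0.05 there were 150 rows, where 116.7 would come by chance. DESeq2 and limma-voom each called 0 rows. The libraries did not overlap in 278 rows (11.9%, against 10% by chance). Among the 887 rows at 100 CPM or more, the 95% interval lay within a 2-fold change in either direction for 816 (92%), and over all tested rows for 967 (41.4%). By row symbol none of the 20 program lists was called: the lowest camera adjusted p was 0.252, for the lysosome list, and MHC class I genes and macrophage identity genes had 0.287 each. In the 2 readings chosen after the data were seen, the lysosome list was called lower in knockout. Read by opposite-strand gene it had an adjusted p of 0.00299 (0.023 with an estimated correlation), and in rows without an opposite-strand exon 0.00961 (0.478 with an estimated correlation). No member passed over all rows in either. Read by opposite-strand gene, MHC class I genes were called higher (0.0428, and 0.0725 with an estimated correlation). By row symbol and adjusted over the list alone, 1 member of all program lists was higher, Tlr1, and 1 lower, Irf5 (opposite Tnpo3). Both are in the pattern recognition list and were chosen after their values were seen. Tlr1 held 6 counts in 1 KO M0 library and 0 in the other 5 M0 libraries. With library size alone as the scale 0 rows were called, and without KO M0 replicate 1 there were 2, the rows opposite Txnip (0.47) and Ccnd1 (−0.74). Without a filter there were 4, Perm1, Cd163, Tctn1 (opposite Hvcn1) and the row opposite Txnip, which were named after their values were seen.

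The fourth comparison asked what the knockout changed in stimulated cells, and no tested row was called at this depth. edgeR called 0 rows, with 164 at an unadjusted p under 0.05 and a lowest adjusted p of 0.291. DESeq2 and limma-voom called 0 as well. Without KO M1 replicate 1 there were 3 calls: Tmem132a, opposite Slc15a3 (log2 fold change −0.38), 4931431C16Rik, opposite the peroxisomal oxidase gene Acox3 (0.58), and Zfhx2os, opposite Zfhx2 (1.01), all named after their values were seen. The Mir6381 row stood at 67470 ± 1537 CPM in KO M1 against 71500 ± 1445 in WT M1, and Cxcl9 at 639 ± 119 against 702 ± 151. Nos2 differed by 0.35 on the log2 scale (standard error 0.41) and Ptgs2 by 0.22 (0.45), neither called. Of the rows at 100 CPM or more, 798 of 887 (90%) had an interval within a 2-fold change, and of all tested rows 914 (39.2%). The libraries did not overlap in 252 rows (10.8%, against 10% by chance). By row symbol no program list was called, with a lowest camera adjusted p of 0.594. In the same reading, adjusted over the list alone, the program lists gave 1 call, Apoe, at −0.51 on the log2 scale (standard error 0.17), named after its values were seen.

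The genotype differences in M0 and M1 were almost unrelated across rows, which are not independent replicates, with a correlation of 0.0287. At an unadjusted p under 0.05 in both states there were 15 rows, 11 of them in the same direction.

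The interaction asked whether the response to LPS and IFN-γ differed between the genotypes. edgeR called 0 rows, with 143 at an unadjusted p under 0.05 and a lowest adjusted p of 0.122, and DESeq2 and limma-voom called 0. That lowest value belonged to the 0610040F04Rik row. It was named after its values were seen and lies opposite Bhlhe40, a transcription factor gene of the circadian clock and of inflammatory macrophages. Its level was 277 ± 74.6 CPM in WT M0, 360 ± 23.4 in WT M1, 163 ± 53.2 in KO M0 and 579 ± 140 in KO M1. The knockout response was larger by 1.45 on the log2 scale (standard error 0.31, 95% interval 0.82 to 2.08). The row was called in 7 of 23 other settings, with adjusted p from 0.000353 to 0.77. Among these were the fits with each of the other filters, and those without WT M0 replicate 2, KO M0 replicate 1, KO M0 replicate 3 or KO M1 replicate 1. The remaining setting was the block for the line label, which called 3 rows, each at an edgeR adjusted p of 0.0243. Besides 0610040F04Rik these were Sphk2, opposite Dbp and Rpl18, and Gm16712, opposite Ebi3 and Yju2, named after their values were seen. Without KO M0 replicate 1 there were 3 calls, which included Mir6381, opposite Gbp2 (−0.62), and Psd, opposite the NF-κB gene Nfkb2 (−0.75), both named after their values were seen. Of the rows at 100 CPM or more, 632 of 887 (71.3%) had an interaction interval within a 2-fold change. By row symbol none of the 20 program lists was called, with a lowest camera adjusted p of 0.879. In the same reading, adjusted over the list alone, 1 member was called, Tlr1, whose M0 level rests on the 6 counts of 1 KO M0 library.

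**Figure D4:**
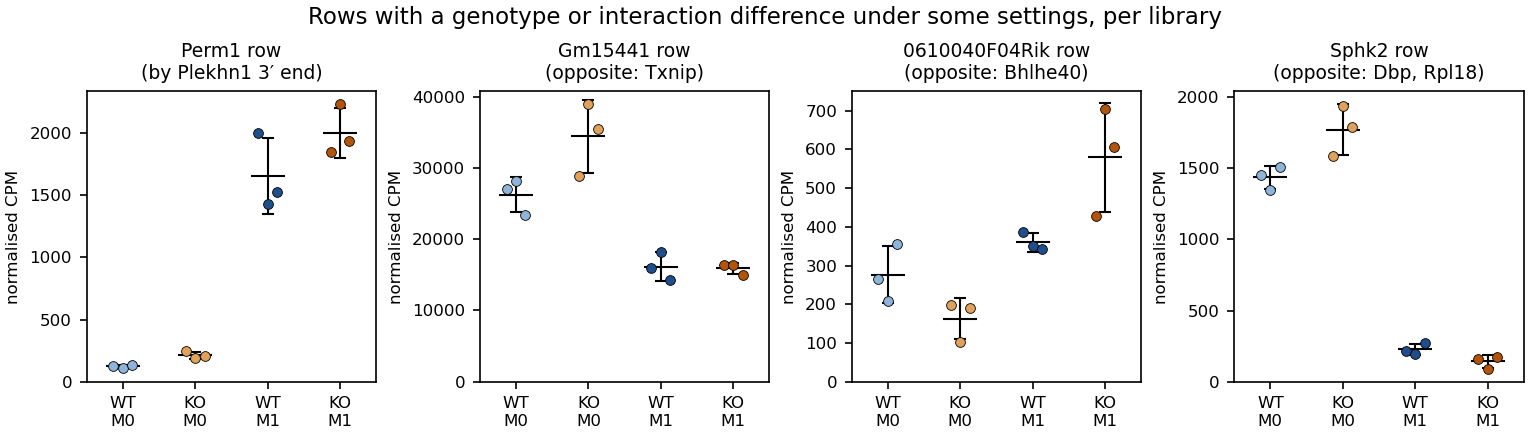
Normalised CPM (y axis, from 0) of 4 rows in each of the 3 libraries of the 4 groups (x axis), with the mean and SD in black. Perm1 averaged 123 CPM in WT M0 and 214 in KO M0, and 0610040F04Rik, opposite Bhlhe40, averaged 360 CPM in WT M1 and 579 in KO M1.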

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

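The tests in this part were chosen after the data were seen.

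The list of MHC class I genes, with members read by the gene on the opposite strand of a row, was called in the interaction of genotype with stimulation. It had a camera adjusted p of 0.0374 over 5 members, all 5 with a negative interaction: −1.46 for Tap1, −1.35 for Psmb9, −0.50 for Erap1, −0.39 for H2-T22 and −0.33 for Nlrc5 on the log2 scale. With an estimated correlation the adjusted p was 0.0862, with fry 0.0391. Only 2 lists had 5 members in this reading, so the adjustment covered 2 tests. None of the 5 genes passed alone, the lowest adjusted p being 0.612, for Tap1. By row symbol the list was not called, with all 20 tested lists at 0.879 or above. Tap1 and Psmb9 lie opposite each other and share the region their rows count. In M0 the list was called toward knockout by camera (adjusted p = 0.0428), was not called with an estimated correlation (adjusted p = 0.0725), and 0 of 5 members passed over all rows, 1 over the list alone. In M1 it was not called (0.568), with members between −0.26 and 0.09. No technical or biological explanation was tested for this list.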

How the results depend on the processing

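The alternatives were fixed first except the 5 settings and 2 list readings named as added after the data were seen. For stimulation, the count of calls stayed within 1.5 times 1138 in wild type and 1110 in knockout under every scaling, filter, tool and removal of 1 library. Removal of 1 library gave 1040 to 1108 calls in wild type and 1016 to 1067 in knockout. Summing rows by opposite-strand gene (added) gave 680 and 662 calls over 1326 genes, and rows without an opposite-strand exon alone (added) gave 360 and 354. Both settings test fewer features. Of 89 called rows named for wild type, 70 passed in all settings and 19 were lost in at least 1. In knockout 78 of 88 passed in all and 10 were lost in some. Acat3 (opposite Tcp1) reversed in wild type, from 0.35 to −0.16 with library size alone. That scale moves the median of all rows by −0.544.

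For knockout against wild type in M0 the single call became 0 with library size alone, DESeq2, limma-voom, the fit of the 2 groups alone, the 2-fold threshold and, among added settings, rows summed by opposite-strand gene, counts halved, without the 10 highest rows, and rows with or without an opposite-strand exon taken apart. The number of calls became 4 without a filter and 3 with the stricter filter. The Perm1 row has no opposite-strand exon and changed by 0.79 on the log2 scale. The summed rows, the rows with such an exon and the 2-fold threshold therefore could not have kept its call and do not test it. Leaving out 1 library gave 0 to 2 calls in M0, 0 to 3 in M1 and 0 to 3 for the interaction. The interaction had 3 calls without a filter and 3 with the stricter filter, the rows 0610040F04Rik, Sphk2 (opposite Dbp and Rpl18) and Fyco1, named after their values were seen. The cause was not tested.

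For the lists, camera called 8 of 20 in each genotype's stimulation, camera with an estimated correlation 4 and fry 13, which asks only whether members move 1 way on balance. Lists read by opposite-strand gene (added, 2 tested) gave 2 calls in wild type, 2 in knockout, 2 in M0 and 1 for the interaction. Lists in rows without an opposite-strand exon (added, 10 tested) gave 5, 5 and, in M0, 1: the lysosome list at 0.00961, with 0.478 under an estimated correlation. In both genotypes the 5 were M1 markers, type I interferon, interferon-γ targets, MHC class I and oxidative stress. Chemokines, pattern recognition and glycolysis were either not tested or not called in this reading. With an estimated correlation, MHC class I and oxidative stress were also lost in wild type (camera adjusted p = 0.154 each). In knockout these (0.171 and 0.111) and interferon-γ targets (0.0626) were lost. The cause was not tested.

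With the replicate number as a replicate block the counts were 1129, 1117, 0 in M0, 0 in M1 and 0 for the interaction. With the line label as a replicate block they were 1113, 1102 and, for the interaction, 3 (0610040F04Rik, Sphk2 and Gm16712, opposite Ebi3 and Yju2). A fit of the line label was not possible between genotypes. Libraries of 1 line label had correlated deviations of 0.0413 to 0.12, with 2 of 6 pairs over 0.1, and of 0.0809 to 0.18 in rows at or above the median level, with 4 of 6 over 0.1. As not every pair passed, the numbers were not taken to pair the samples. As a hint from the data, among libraries of the same genotype 12 of 12 correlated best with their own line label in the other state, and among both genotypes 7 of 12. The 4 libraries that stood apart in the sex-linked list also carried 1 replicate number. Whether a number marks 1 animal stays open, so the interaction is given with and without the block. The list mean of log2 CPM was not run. Depth limits what can be seen: in M0, 10.4% of rows under 100 CPM had an interval within a 2-fold change.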

Other observations

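Apart from the splits of the samples, the tests in this part were chosen after the results were seen. Rows summed by their opposite-strand gene gave these changes with stimulation in wild type, chosen after their values were seen. On the log2 scale, with standard errors, Gbp2 changed by 9.14 (0.16), Psmb9 by 7.10 (0.49), Il1a by 5.87 (0.36), Nlrc5 by 4.30 (0.24) and Hk3 by 3.83 (0.14). Csf1r changed by −2.48 (0.18), Ctsb by −2.51 (0.10), Stab1 by −2.79 (0.14), Kif20a by −3.23 (0.41) and Ccna2 by −4.13 (0.53). The list of lysosome genes in this reading fell in 5 of 6 members in wild type (camera adjusted p = 3.79e-06, and 0.00238 with an estimated correlation) and was lower in M0 knockout cells as a list (0.00299, and 0.023 with an estimated correlation) with 0 of 6 members passing.

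Of 12 lists for other cell types, 9 had no member among the tested rows and none had 5. In the remaining lists, sums over 3 libraries in M0 and M1 were, for the dendritic cell genes Xcr1 and H2-Ab1, 42 and 662 and 6 and 79 in wild type, and 33 and 656 and 9 and 75 in knockout. Clec9a, of the same list, went from 17 to 1 in wild type and from 29 to 0 in knockout. An exon of its row lies 9 bases past the opposite-strand 3′ end of Clec1a. The monocyte gene Itga4 (opposite Cerkl) went from 202 to 64 and from 191 to 46, and the progenitor gene Procr from 0 to 58 and from 0 to 49. Camera was run on 2 of 6 technical lists, ribosomal proteins and immediate early genes, and called neither in any comparison. By fry the immediate early list had an adjusted p of 0.0451 in wild type, with 4 of 6 members up and 1, Jund (opposite Gm11175), down (a call lost in 4 of 18 other settings), and 0.00617 in knockout, with 5 of 6 up. Adjusted over the list alone, 1 also fell in knockout. In the sex-linked list, 1 library in each of the 4 groups stood apart from the other 2, so the groups are balanced, and these 4 libraries carry 1 replicate number. Among counts from 1 to 12, 60.9% were even, with 9131 counts of 1 and 14802 counts of 2.

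A first pattern is that counts lie in rows with a gene on the opposite strand. Of matched rows with 100 to under 1000 counts, 89.4% had an opposite-strand exon, which is consistent with reads counted on the strand opposite to their gene, a possible outcome for a strand-specific kit. Reads shared by overlapping genes in counting without strand would leave the ribosomal protein genes abundant, and their rows held 0.0546% of the counts, which argues against that. No biological explanation was tested. The strand setting used by the authors is not given, so the first explanation stays a hypothesis.

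A second pattern is that few rows differ between the genotypes. Too few counts to exclude a 2-fold difference is argued against for rows at 100 CPM or more, where 92% of intervals in M0 lay within it, and stays open for rows under 100 CPM, where 10.4% did. Exchanged knockout and wild-type labels cannot be told apart from correct ones by the 6 counts of Gpr31b in wild-type libraries against 0 in knockout. A small effect of the receptor under these culture conditions stays open as an untested biological explanation. The pattern covers only the 2333 tested of 24552 rows, and genes that macrophages express strongly had few counts in their own rows. An effect on genes without a tested row therefore stays open too.

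With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For wild-type stimulation 1 split gave as many rows as the real 1138, the highest other being 0, and for knockout stimulation 1 gave 1110, the highest other being 0. In M0 the real split had 1 row and 2 splits had as many, the highest other being 3. In M1 and for the interaction the real value was 0, so all 10 splits had as many, with 1 and 0 as the highest others.

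The last pattern is the interaction of the 0610040F04Rik row, opposite Bhlhe40. If 1 library out of place made it, the interaction would vanish without that library, but its lowest value with each library left out in turn was 1.21 on the log2 scale. The row was picked for its low p, and these fits reuse the libraries that picked it, so chance stays open. Nor do they test a line label out of place. The KO M0 and KO M1 libraries of replicate 2 stood at 101.9 and 703.2 CPM, the lowest and the highest of their groups. Libraries taken at different phases of the circadian clock may shift Bhlhe40, and the Thra row, opposite Nr1d1, had an interaction of −0.75 with a standard error of 0.89, too wide to decide. Of the other clock genes with a row, the D930015M05Rik row, opposite Cry2, had −0.91 (0.47) and the Gm15511 row, opposite Rora, 0.47 (0.78). The Sphk2 row, which Dbp and Rpl18 share, had −0.97 (0.23, edgeR adjusted p = 0.177, 0.0222 to 0.77 over alternatives). The intervals of the rows opposite Cry2 and Rora spanned both signs, so the signs of these estimates do not decide about a shift of phase. An effect of the knockout stays open as well.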
